A study of Mus musculus with 12 samples.

How the data were processed

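RNA was measured in whole hippocampi of male C57Bl/6 mice aged 12 weeks. Per the labels' protocols, the tissue was frozen at dissection, RNA was extracted with TRIzol and a column cleanup, polyadenylated RNA was selected on oligo d(T) beads, and libraries made with a NEBNext Ultra kit were sequenced as single reads on an Illumina instrument. The labels give 6 control and 6 toxicant samples from different animals and name no sequencing or dissection batch.

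The deposited table held 1 RPKM value (reads scaled to the length of the gene model in kilobases and to sequencing depth) for each of 41743 genes in each of 12 libraries, per the file headers. Each column was matched to its sample through the short code in the sample's description. The aligner, the counting program, the genome build and the annotation are not given in the sources used here. No count table was used here.

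The columns of control 4 and control 5 held identical values in every gene, while no other pair of columns did. They were counted once, as the library control 4-5, so that 5 control and 6 toxicant libraries entered each test. The design had named 12 samples, and the fit with all 12 is among the alternatives.

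The depth behind the values was recovered from the RPKM steps. Multiplied by the summed exon length of the gene in GENCODE M21 (GRCm38), the values of a library were whole multiples of 1 unit, the worth of 1 read. Between 98.3% and 98.5% of a library's values came out whole within 0.05 reads. This gave 21.5 M to 34.9 M reads behind the RPKM scale of a library (median 27.03 M), of which 76.8% to 89.5% lay on the genes of the table. The remainder is called reads outside the annotated exons below. Of the 41743 gene IDs, 41675 were found in GENCODE M21, which was used for exon lengths, GC content, gene classes and positions. The authors' build is not named, so positions are those of GRCm38 looked up by Ensembl ID. A gene past the filter on low values had a median of 569 reads per library, so counting error was small beside the spread between animals for most genes. The library kit's strandedness is not stated, so a gene and its antisense partner may share reads.

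Values were analysed as log2(RPKM + 0.5), and fold changes are on that scale, which understates the change of low genes. Genes with a mean of at least 0.5 RPKM over the 11 libraries were tested (13493 genes). Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided), with no covariate, Benjamini-Hochberg adjustment and a threshold of 0.05. RPKM values are not counts, so no count model was applied to them as the main test.

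Before the data were examined, 51 gene lists were written that cover the targets of the 3 compounds, stress and immune responses, synaptic and ion channel genes, energy metabolism, cell types of the hippocampus and tissues next to it. Of 1260 list symbols, 1238 were found in the table. Lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 49 lists tested. The sex-linked list served as a check of the labels, and the list of peripheral leukocyte genes had 1 member past the filter and was not tested. Beside camera, each list was tested with a correlation estimated from the data and with fry. A list score per library is the mean log2 value of its members minus the mean of all tested genes. Whole-transcriptome structure was tested by an exact permutation of the group labels over the first 2 principal components, and the cholinesterases Ache and Bche and the acetylcholine-synthesising enzyme Chat by an exact permutation test over all 462 splits of the 11 libraries, two-sided and adjusted over the 3.

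The rule for the genes named was fixed in advance. It took the genes past the threshold with the largest change and the smallest p, and where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p in that direction. It added the 4 members with the smallest p of each list called by camera, and 17 genes fixed by name: Ache, Bche, Chat, Chrm1, Fos, Arc, Npas4, Egr1, Fkbp5, Sgk1, Gfap, Aif1, Il1b, Tnf, Mbp, Bdnf and Ttr. Predicted genes without a proper name and pseudogenes were left out of the first part of the rule. Genes named outside it are said to be so, and 1 gene that the rule takes is not reported here.

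Alternatives fixed in advance were other pseudocounts (0.1 and 1), no filter and a filter at 1 RPKM, median-ratio scaling, quantile normalization, other variance models, sample weights, the replicate number as a block, the first principal component of the residuals as a covariate, the choroid plexus score as a covariate, leaving out each library in turn, an adjusted threshold of 0.1, a minimum log2 change of 0.25, and an exact rank-sum permutation test. Alternatives chosen after seeing the data were the 12 libraries as deposited, the share of reads on genes as a covariate (with the preset and, for lists, also an estimated correlation), the nuclear RNA list as a covariate, removal of each library's trend on exon GC content, limma voom on the recovered reads (13212 genes whose reads were whole in every library), and an exact permutation of list scores. For count-based results, 100 splits of the libraries into groups of the same sizes were drawn, the real one included.

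The steps were tested on simulated data with 200 changed genes among the 13493 (10 simulations). With independent noise, the limma fit recovered 50.2% of changes of log2 0.5 and 89.9% of changes of log2 1, with a mean of 7.6 false calls. With noise correlated between genes as in these libraries, it recovered 46.0% and 91.1%, with a mean of 498 and at most 4793 false calls. With the first residual component as a covariate the mean of false calls was 2205 under that noise, so the counts of that alternative are not reliable. A list shifted by log2 -0.3 was called by camera at the preset correlation in 10 of 10 simulations under either noise. With independent noise 0 other lists were called, and with noise as in these libraries a median of 7 and at most 9 of the other lists were called. With an estimated correlation under that noise the shifted list was called in 7 of 10 simulations and at most 1 other list was. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading the table and for plots.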

Results

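Gene expression in the hippocampus was measured by RNA-seq in male mice after 2 weeks of exposure to a mixture of chemicals encountered in the Gulf War, or to vehicle. The mixture was 2.5 mg/kg pyridostigmine bromide, a reversible inhibitor of cholinesterase given to soldiers as a pretreatment against nerve agents, 12.5 mg/kg chlorpyrifos, an organophosphate insecticide that inhibits cholinesterase, and 7.5 mg/kg DEET, an insect repellent. Tissue was taken when the exposure ended. The question was which transcripts differ between exposed and vehicle-treated animals.

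Of 12 deposited libraries, the values of control 4 and control 5 were identical. They differed by less than sampling noise could give and were counted as 1 sample, which left 5 control and 6 toxicant libraries. The reads behind the RPKM values came to 29.6 M ± 3.61 M (SD, n = 5) in control and 24.7 M ± 2.68 M (SD, n = 6) in toxicant libraries, with 20622 to 22459 genes detected per library. The share of reads that lay on genes was 85.4% ± 4.58 (SD, n = 5) in control and 80.8% ± 2.68 (SD, n = 6) in toxicant libraries (exact permutation p = 0.0714). Xist was at or below 0.0478 RPKM and Ddx3y at or above 2.76 RPKM in each library, as in male tissue.

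In toxicant hippocampi, activity-induced immediate early genes and oligodendrocyte, microglial and endothelial genes were lower as groups by camera at a preset correlation between genes, while no single gene passed the adjusted threshold. None of these 4 groups passed camera with an estimated correlation (adjusted p = 0.797 each). By an exact permutation of list scores their p was 0.00433 to 0.0130 unadjusted and 0.0606 to 0.0707 adjusted. With 462 splits that test allows no p under 0.00216, so adjustment over 49 lists leaves it little room to pass. With fry, which sets a list against no change, all 4 passed (adjusted p = 0.00859 to 0.0215). Of 33 immediate early genes, transcribed within minutes of neuronal activity, 28 were lower, and the median log2 fold change was -0.26. Of 26 oligodendrocyte and myelin markers, 23 were lower, with a median of -0.43. These 2 medians were -0.17 and -0.29 with the share of reads on genes as a covariate and -0.11 and -0.30 with each library's GC trend removed, where the medians over all genes were -0.03 and -0.0029. Across the 13493 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.0715. At an unadjusted p under 0.05 there were 2737 genes, 449 higher and 2288 lower, where 675 are expected by chance. The median log2 fold change over all genes was -0.11, and it was -0.02 after median-ratio scaling. The fold changes and the counts of lower genes are to be read against that shift. Below the all-gene median lay 24 of the 33 immediate early genes and 21 of the 26 oligodendrocyte markers. An exact rank-sum permutation test called 0 genes, with 289 genes at its smallest possible p of 0.00433, where 58.4 are expected by chance, and limma voom on the recovered reads called 0.

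Among the immediate early genes, 13 fell and 1 rose when p was adjusted over the list alone, and 0 passed over all genes tested. Arc, an effector of synaptic plasticity, was at 37.0 ± 5.64 RPKM (SD, n = 5) in control and 20.04 ± 3.59 RPKM (SD, n = 6) in toxicant libraries, a log2 fold change of -0.87 ± 0.14 (SE, limma adjusted p = 0.0715). All 6 toxicant libraries lay below the lowest control. Arc (ENSMUSG00000022602) spans chromosome 15 from 74669083 to 74672570 and Egr1 (ENSMUSG00000038418) chromosome 18 from 34859823 to 34864984 in GRCm38 (GENCODE M21). The transcription factor Egr1 went from 25.2 ± 3.98 to 14.4 ± 2.76 RPKM (log2 fold change -0.79 ± 0.13) and Fos from 4.37 ± 0.418 to 2.56 ± 0.609 RPKM (-0.69 ± 0.12), each with 6 of 6 toxicant libraries below the lowest control. Btg2, an antiproliferative gene induced by activity, was at 4.93 ± 0.682 and 3.13 ± 0.193 RPKM (-0.57 ± 0.09). Npas4, an activity-dependent transcription factor, was at 1.55 ± 0.895 and 1.07 ± 0.0902 RPKM, a log2 fold change of -0.29 ± 0.21 that was smaller than the spread between control libraries . It was -0.07 without control 2, which was at 3.06 RPKM, -0.46 without control 6 and -0.61 with the share of reads on genes as a covariate. The list was called by camera (adjusted p = 0.000609; adjusted p = 0.797 with an estimated correlation).

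Opalin and Mog, both specific to myelinating oligodendrocytes, were at 6.07 ± 0.540 and 23.9 ± 3.01 RPKM in control and at 3.55 ± 0.550 and 16.4 ± 1.96 RPKM in toxicant libraries, log2 fold changes of -0.71 ± 0.10 and -0.53 ± 0.11. Mbp, a major protein of compact myelin, was at 289 ± 38.9 and 195 ± 25.4 RPKM (-0.56 ± 0.12), with 6 of 6 toxicant libraries below the lowest control. Apod, a lipid-binding protein, was at 27.8 ± 2.20 and 18.1 ± 1.99 RPKM (-0.61 ± 0.09), and the receptor Gpr37 at 9.91 ± 1.44 and 6.92 ± 0.751 RPKM (-0.48 ± 0.10). Opalin (ENSMUSG00000050121) lies on chromosome 19 from 41061710 to 41077113 and Mbp on chromosome 18 from 82475146 to 82585637 in GRCm38. Of the 26 markers 17 fell when adjusted over the list alone and 0 passed over all genes (camera adjusted p = 3.48e-06; adjusted p = 0.797 with an estimated correlation). The 19 oligodendrocyte precursor markers had a median of -0.09 and were not called (camera adjusted p = 0.870). The oligodendrocyte score minus the precursor score was lower by -0.25 in toxicant libraries (exact permutation p = 0.00433).

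**Figure D1:**
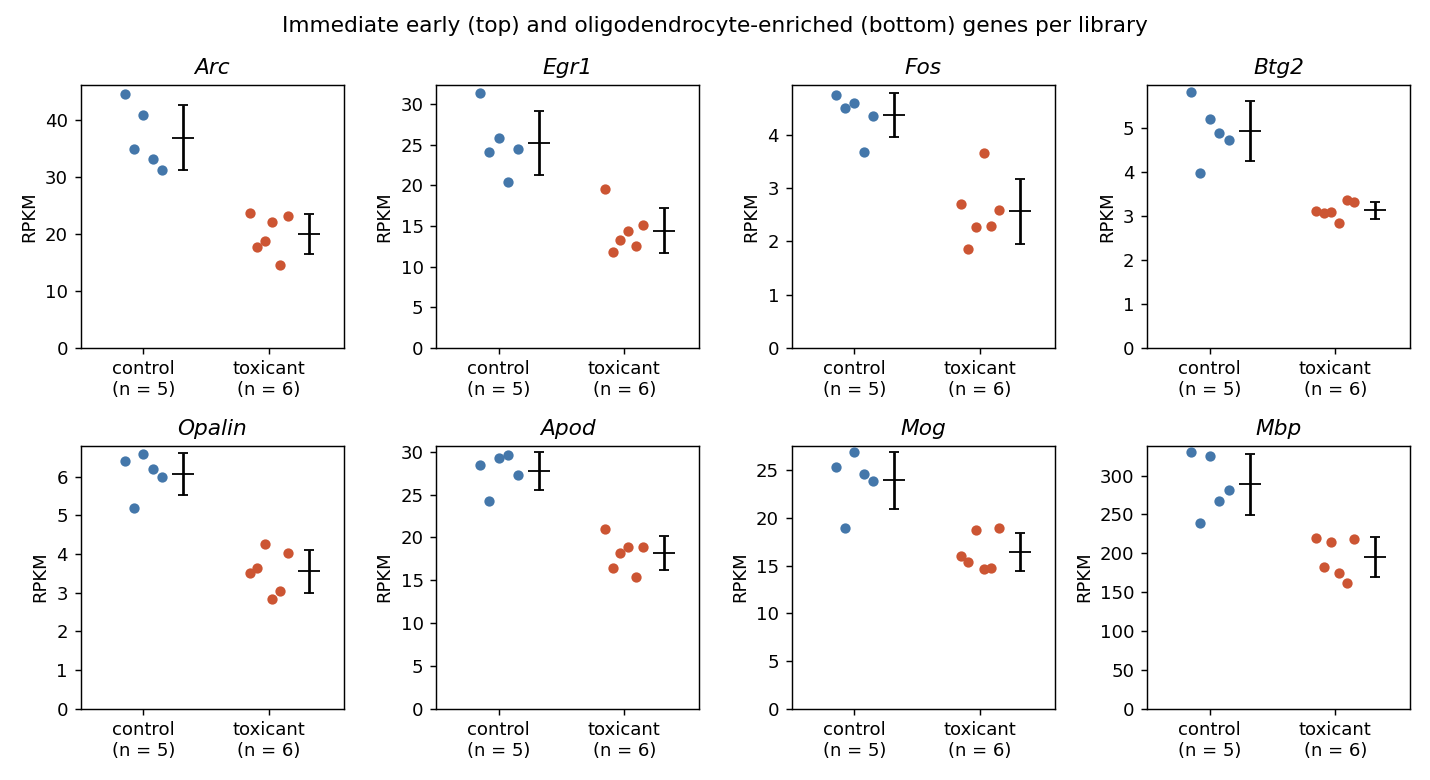
RPKM per library (y axis, starting at 0) of 4 immediate early genes (top row) and 4 oligodendrocyte-enriched genes (bottom row) in 5 control (blue) and 6 toxicant (orange) libraries. The black marks are the mean and SD, and for Arc, Egr1, Fos, Btg2, Opalin, Apod and Mbp all 6 toxicant libraries lie below the lowest control.

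Homeostatic microglia markers were lower in 20 of 20 genes, with a median log2 fold change of -0.27, and 12 fell when adjusted over the list alone. The integrin Itgam was at 3.13 ± 0.207 and 2.35 ± 0.330 RPKM (-0.36 ± 0.09), the protease Ctss had a log2 fold change of -0.27 ± 0.08 and the receptor Csf1r one of -0.30 ± 0.10. The median was -0.10 and the log2 fold change of Csf1r -0.11 with the share of reads on genes as a covariate, and the median was -0.12 with the GC trend removed. This list was called by camera (adjusted p = 0.000418; adjusted p = 0.797 with an estimated correlation). Aif1, another microglial gene, had a log2 fold change of -0.07 ± 0.14, whose sign turned under median-ratio scaling and without control 3 or toxicant 1. Endothelial and blood-brain barrier markers were lower in 22 of 26 genes (median -0.20), and 11 fell when adjusted over the list alone. The adhesion molecule Pecam1 was at 1.73 ± 0.149 and 1.20 ± 0.126 RPKM (-0.39 ± 0.08), the endothelial cadherin Cdh5 at 2.30 ± 0.235 and 1.71 ± 0.10 RPKM (-0.34 ± 0.07), and the receptor Tek and the surface glycoprotein Cd34 had log2 fold changes of -0.39 ± 0.09 and -0.33 ± 0.08. Camera called the endothelial list at an adjusted p of 0.000799 (adjusted p = 0.797 with an estimated correlation), and without control 2 the adjusted p was 0.0684. With the share of reads on genes as a covariate the endothelial median was -0.21. The score difference of that list went from -0.15 to -0.17 ± 0.05 SE (camera adjusted p = 4.55e-06, and 0.295 with an estimated correlation). With the GC trend removed the endothelial median was -0.16. Cxcl12, a chemokine, was at 5.82 ± 0.720 and 3.97 ± 0.244 RPKM (-0.49 ± 0.08), with 6 of 6 toxicant libraries below the lowest control.

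Genes that mark reactive astrocytes were lower in 14 of 16 cases (median -0.22), of which 7 fell when adjusted over the list alone. Gfap, the intermediate filament of astrocytes, was at 61.6 ± 9.96 and 46.8 ± 3.76 RPKM (-0.38 ± 0.11), and the filament gene Vim at 6.61 ± 0.957 and 4.99 ± 0.429 RPKM (-0.37 ± 0.10). The class I histocompatibility gene H2-D1 and the complement inhibitor Serping1 had log2 fold changes of -0.48 ± 0.10 and -0.46 ± 0.10. With the share of reads on genes as a covariate the score difference of the list went from -0.18 to -0.09 and the log2 fold changes of Gfap, Vim and H2-D1 were -0.17, -0.19 and -0.29. The list was called at a camera adjusted p of 0.0170 (adjusted p = 0.797 with an estimated correlation), and the call was lost without control 2, without control 4-5 or without toxicant 3 (adjusted p up to 0.0839). Of 22 general astrocyte markers 18 were lower, with a median of -0.19 and no call (camera adjusted p = 0.0765).

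Ribosomal protein genes were lower in 40 of 40 cases (median -0.26), nuclear-encoded genes of oxidative phosphorylation in 36 of 37 (median -0.21) and genes of the NRF2 antioxidant response in 23 of 25 (median -0.22). Of these, 0, 0 and 4 fell when adjusted over the list alone. Rpl7a had a log2 fold change of -0.35 ± 0.12, Rps24 of -0.22 ± 0.08, Rpl22 of -0.27 ± 0.11 and Rpl10a of -0.26 ± 0.10. Among respiratory chain subunits the log2 fold changes were -0.24 ± 0.08 for Ndufv2, -0.25 ± 0.09 for Uqcrc2, -0.29 ± 0.12 for Ndufa10 and -0.29 ± 0.13 for Sdhc. Of the antioxidant genes, the peroxiredoxin Prdx1 was at 26.3 ± 2.12 and 20.4 ± 1.33 RPKM (-0.36 ± 0.08), the ferritin heavy chain Fth1 at 488 ± 61.2 and 374 ± 37.9 RPKM (-0.38 ± 0.11), and G6pdx and catalase (Cat) had log2 fold changes of -0.37 ± 0.11 and -0.26 ± 0.08. The camera adjusted p was 0.000353 for the ribosomal, 0.0441 for the respiratory and 0.0304 for the antioxidant list (adjusted p = 0.829, 0.911 and 0.826 with an estimated correlation). With the share of reads on genes as a covariate the medians were -0.01, 0.03 and -0.02, and the respiratory list was called higher (camera adjusted p = 0.00136). After removal of the GC trend they were -0.11, -0.09 and -0.13. The antioxidant call was lost without toxicant 3 (camera adjusted p = 0.0660). The respiratory call was lost without control 1, 3 or 6 or toxicant 2, 3 or 4 (camera adjusted p up to 0.140). Both calls were also lost with quantile normalization and with a filter at 1 RPKM. The respiratory median was -0.13 without control 1 and -0.32 without control 2.

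The 1 list called higher was that of long noncoding and nuclear-retained RNA, with 10 of 13 members higher, a median of 0.29 and 0 members past the test over the list alone (camera adjusted p = 0.000799; adjusted p = 0.797 with an estimated correlation). The median was 0.13 without control 1 and 0.46 without control 2. Malat1, a nuclear transcript, was at 154 ± 127 and 258 ± 77.0 RPKM (1.09 ± 0.45) and Meg3 at 99.7 ± 78.7 and 146 ± 50.5 RPKM (0.81 ± 0.43, and 0.52 without control 1). The noncoding RNA Gm26917 had a log2 fold change of 0.55 ± 0.17, and Peg13 went the other way (-0.33 ± 0.13). With the share of reads on genes as a covariate the median of the list was -0.18. The log2 fold change was then 0.07 for Malat1, -0.18 for Meg3 and -0.07 for Peg13. That of Gm26917 did not shrink (0.59), and all 6 toxicant libraries lay above the highest control for it.

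**Figure D2:**
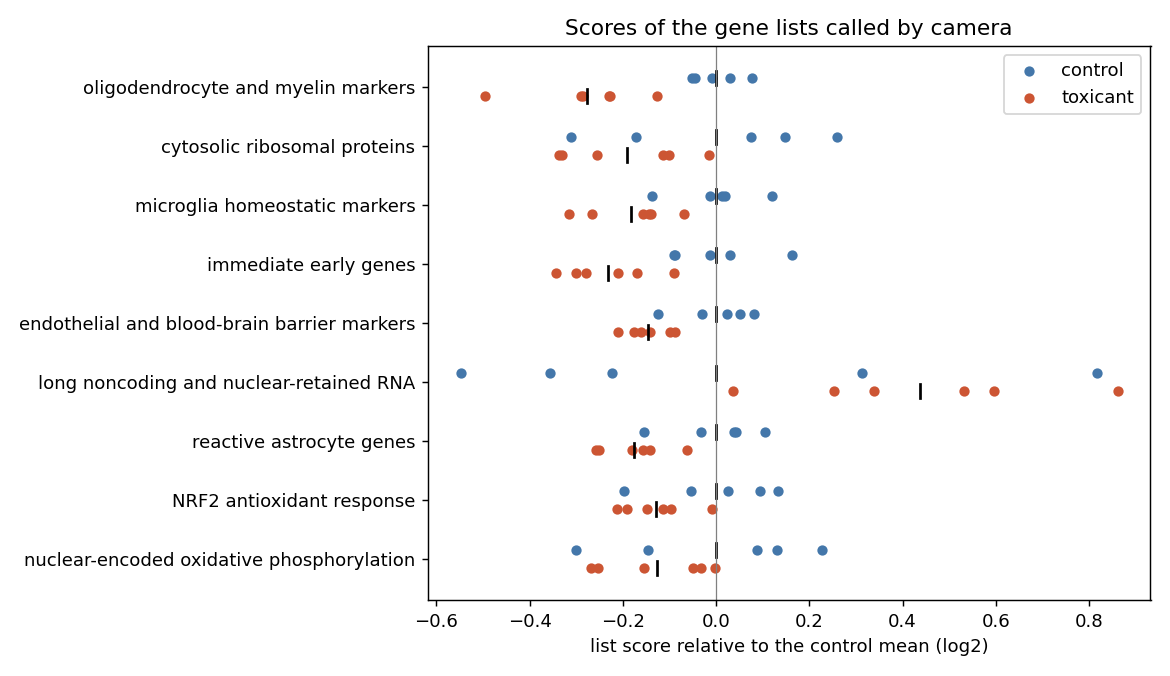
Score per library (x axis, log2, relative to the control mean) of the 9 gene lists called by camera in 5 control (blue) and 6 toxicant (orange) libraries, with vertical black marks at the group means. All 6 toxicant libraries lie below every control library for the oligodendrocyte and myelin markers, whereas the groups overlap in each of the other lists shown. For the immediate early genes the overlap is narrow.

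The genes with the smallest p among those higher in toxicant libraries were mostly short noncoding RNAs, and none passed the adjusted threshold. The small nucleolar RNA Snord91a was at 1.06 ± 0.542 and 2.77 ± 0.657 RPKM (log2 fold change 1.12 ± 0.22, limma adjusted p = 0.153), with a mean of 4.82 reads per library. Rn7sk, a regulator of transcription elongation, was at 92.1 ± 23.6 and 151 ± 25.3 RPKM (0.73 ± 0.17). Rmrp, the RNA of a mitochondrial and ribosomal RNA-processing enzyme, had a log2 fold change of 0.93 ± 0.22 and the 5S ribosomal RNA gene n-R5s130 one of 1.31 ± 0.31. The protein-coding Unc5d, a netrin receptor, was at 1.88 ± 0.309 and 2.76 ± 0.418 RPKM (0.45 ± 0.11).

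Transcripts of the cholinesterases Ache and Bche and of Chat did not pass the test, and enzyme activity was not measured here. Ache, which encodes acetylcholinesterase, was at 12.5 ± 2.09 RPKM (SD, n = 5) in control and 10.9 ± 0.708 RPKM (SD, n = 6) in toxicant libraries, a log2 difference of -0.18 (exact permutation p = 0.115, adjusted p = 0.344). That difference was -0.10 without control 1, and without control 2 it was -0.26 and passed (exact permutation, adjusted p = 0.0286). It was -0.0044 with the share of reads on genes as a covariate (limma adjusted p = 0.988). Bche, which encodes butyrylcholinesterase, was at 0.488 ± 0.256 and 0.503 ± 0.0956 RPKM (exact permutation p = 0.766), and Chat at 0.0169 ± 0.0149 and 0.00850 ± 0.00944 RPKM (exact permutation p = 0.273). Both genes were under the filter on low values. Chat had a mean of 1.55 reads per library, so its test says little. Chrm1, the main muscarinic receptor of the hippocampus, had a log2 fold change of -0.35 ± 0.12 (limma adjusted p = 0.217). This was -0.44 without control 2 (limma adjusted p = 0.0230) and -0.10 with the covariate (limma adjusted p = 0.430). In the cholinergic list 10 of 13 genes were lower (median -0.14, camera adjusted p = 0.787), and 7 of 13 lay below the all-gene median. The serine hydrolases sensitive to organophosphates (13 of 16 lower, 9 below the all-gene median, adjusted p = 0.514) were not called by camera. Neither were the genes of xenobiotic metabolism (17 of 21 lower, 12 below that median, adjusted p = 0.175). The xenobiotic list passed with fry (adjusted p = 0.0151). The exact permutation p of its score was 0.00216, the smallest that 462 splits can give (adjusted p = 0.0606).

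Apart from the antioxidant and reactive astrocyte lists above, stress and inflammation lists were not called by camera. The glucocorticoid-responsive list had 16 of 25 genes lower and 11 below the all-gene median (camera adjusted p = 0.936). Adjusted over the list alone, 5 fell and 1 rose. The log2 fold change was -0.41 ± 0.17 for Sgk1 and -0.01 ± 0.11 for Fkbp5. The sign for Fkbp5 turned under median-ratio scaling, quantile normalization and with the share of reads on genes as a covariate (0.22). It also turned without control 1 or 3 or toxicant 2 or 4. Cytokine, chemokine and NF-kB genes were lower in 16 of 18 cases (camera adjusted p = 0.0596) and interferon response genes in 14 of 17 (camera adjusted p = 0.0765). Of these, 12 and 11 lay below the all-gene median, and 2 and 6 fell when adjusted over the list alone. Both lists passed with fry (adjusted p = 0.0134 and 0.00859). The exact permutation p of their scores was 0.00649 and 0.00433 (adjusted p = 0.0606 each). Il1b was at 0.106 ± 0.0491 and 0.124 ± 0.0565 RPKM and Tnf at 0.0644 ± 0.0453 and 0.0398 ± 0.0354 RPKM, both under the filter. The neurotrophin gene Bdnf was at 4.81 ± 0.289 and 4.55 ± 0.363 RPKM (-0.07 ± 0.07), with the opposite sign under median-ratio scaling.

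Markers of neuron classes and of adjoining tissue were not called by camera. Dentate granule cell markers were lower in 20 of 24 genes (camera adjusted p = 0.0765), CA1 markers in 11 of 19 (adjusted p = 0.438) and CA2 and CA3 markers in 19 of 28 (adjusted p = 0.995). Below the all-gene median lay 16, 11 and 13 of these. Adjusted over the list alone, 6 dentate markers fell, 2 CA1 markers rose and 2 fell, and 0 CA2 and CA3 markers passed. With fry the dentate list (adjusted p = 0.0496) and the neocortex list (adjusted p = 0.0242) passed as lower. Choroid plexus markers had a median of -0.47, with 17 of 18 lower (adjusted p = 0.995), and their leading gene Ttr ranged from 12.9 to 2836 RPKM between libraries, at 721 ± 1209 and 322 ± 707 RPKM in the 2 groups. Over the whole transcriptome the first principal component held 58.5% of the variance and the second 11.1%, and neither separated the groups (exact permutation p = 0.121 and p = 0.141). The first component followed the share of reads on genes over the 11 libraries (Pearson's r = -0.969, permutation p = 1e-05, the smallest that 100000 resamples can give; adjusted p = 3e-05 over 6 relations; Spearman's rho = -0.991, permutation p = 1e-05). Without the 2 libraries farthest from the median r was -0.975, and within the 6 toxicant libraries it was -0.909 (exact permutation p = 0.0125). No correlation was computed within the 5 control libraries. The values within toxicant libraries, here and below, therefore do not show how the controls behave. The share and the component come from the same values, and a lower share lowers RPKM over the genes as a whole. Part of their relation is therefore built in. The ribosomal score rose with that share (r = 0.956, rho = 0.918, permutation p = 2e-05 and 0.00021; without the 2 farthest libraries r = 0.937; within toxicant libraries r = 0.894, exact permutation p = 0.0139). The immediate early score also rose with it (r = 0.755, rho = 0.773, permutation p = 0.00789 and 0.00764, adjusted p = 0.00947). For this score r was 0.725 without the 2 farthest libraries and 0.332 within toxicant libraries (exact permutation p = 0.507). For the oligodendrocyte score r was 0.582 and rho 0.682 (permutation p = 0.0601 and 0.0246, adjusted p = 0.0601). There r was 0.451 without the 2 farthest libraries and 0.0832 within toxicant libraries (exact permutation p = 0.882). Among the controls, control 2 had the lowest share (78.4%) and also the lowest immediate early and oligodendrocyte scores (0.44 and 1.90).

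**Figure D3:**
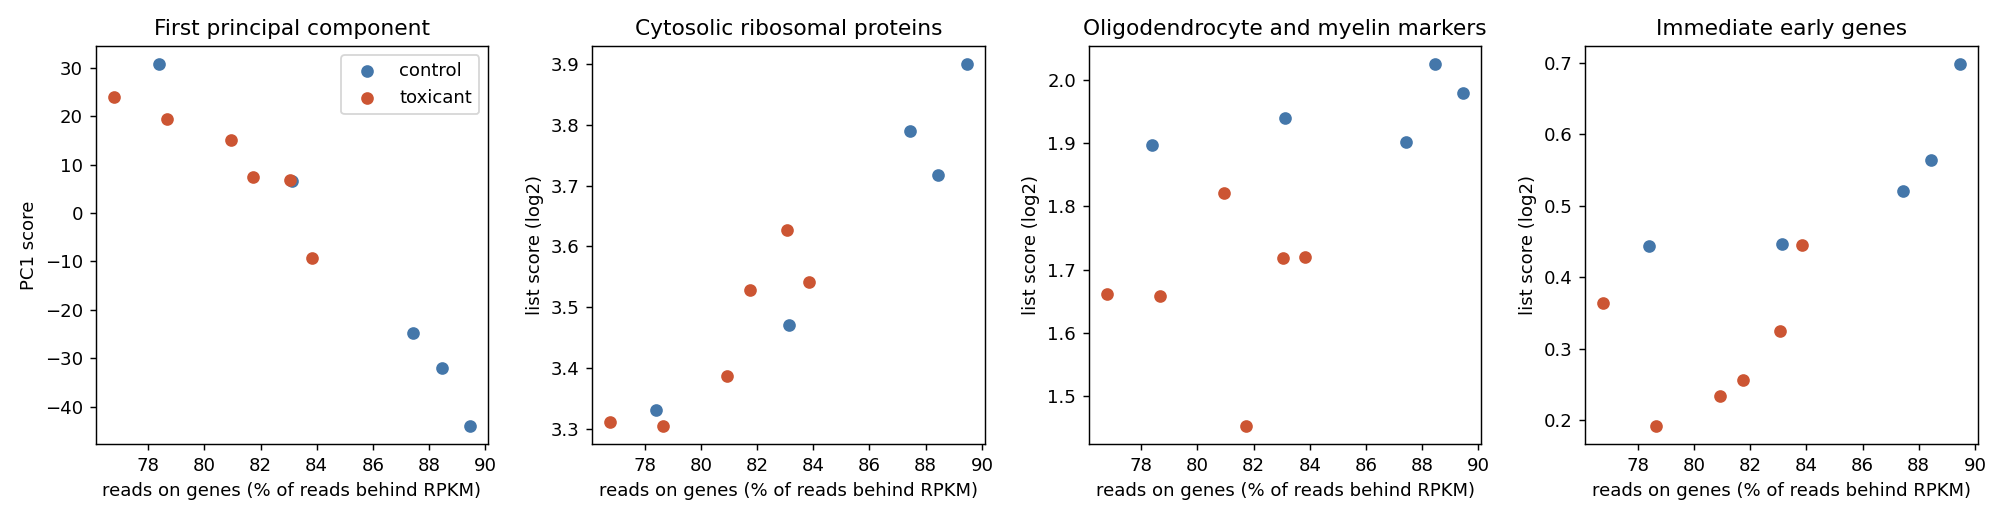
Share of reads on genes (x axis, % of the reads behind the RPKM values) against the first principal component score and the log2 list scores of ribosomal protein, oligodendrocyte and immediate early genes (y axes), 1 point per library, 5 control (blue) and 6 toxicant (orange). The first component and the ribosomal score follow the share over the 11 libraries. The oligodendrocyte scores of the groups stay apart at like shares, and the immediate early scores lie between these cases, rising with the share over the 11 libraries.

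The camera calls rest on the preset correlation, since 0 of the 9 calls held with an estimated correlation. Simulated libraries with noise as in these had a median of 7 unshifted lists called at the preset correlation. Fry, which uses no preset correlation, called 18 lists, all lower. Among them were the oligodendrocyte, endothelial, immediate early, reactive astrocyte and microglia lists (fry adjusted p = 0.00859 to 0.0215). It sets a list against no change and not against the other genes, whose median log2 fold change was -0.11. An exact permutation of list scores passed 0 lists after adjustment (smallest adjusted p = 0.0606). Its 462 splits allow no p under 0.00216, which leaves little room over 49 lists, and 15 lists had an unadjusted p under 0.05. The count of single genes rested on 1 library, since without control 2, which had the lowest share of reads on genes among the controls (78.4%), 1153 genes were higher and 3779 lower, and it also changed with sample weights, which ran from 0.132 for control 2 to 12.5 for control 6, to 2863 higher and 6690 lower.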

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

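The tests of the share of reads on genes, of GC content and of non-neuronal cells, and the counts of splits for genes past the adjusted threshold and for the highest count over libraries left out, were chosen after the results were seen. The tests of clock genes and exon length and the other counts of splits were set out before their results were seen.

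Among 146 groups of values checked, 9 held 1 library far from the others of its group, where chance gives about 7. Ttr was at 2836 RPKM in control 3 (the other controls at 13.6 to 629) and at 1764 RPKM in toxicant 2 (the others at 12.9 to 55.7). Prdx1 was at 22.5 RPKM in control 2 (the others at 27.0 to 27.5) and at 17.9 RPKM in toxicant 4 (the others at 20.3 to 21.5). Bche was at 0.933 RPKM in control 2 against at most 0.431 in the other controls. Pecam1 was at 1.47 RPKM in control 6 against at least 1.75, and Cd34 at 4.65 RPKM in control 1 against at most 4.21. Gm26917 was at 85.7 RPKM in toxicant 4 against at most 55.8. On the second principal component toxicant 2 was at -14.4, with the other toxicant libraries at 3.26 to 11.9.

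Immediate early genes were lower in toxicant libraries by a score of -0.23 ± 0.06 SE. With each library's GC trend removed the difference was -0.19 ± 0.04 (camera adjusted p = 4.5e-06 at the preset correlation, none being computed with an estimated one). The score followed the share of reads on genes (r = 0.755 over 11 libraries), and with that share as a covariate the difference was -0.16 ± 0.06 (camera adjusted p = 0.00335; adjusted p = 0.295 with an estimated correlation). Without control 2 it was -0.13 ± 0.09, under 2 SE, so the share cannot be told apart from the exposure, because 1 library decides the test. The clock genes with Per2 and Dbp and those with Arntl, which another time of collection would move against each other, differed by -0.06 and 0.04 from control (exact permutation p = 0.154 for the difference between them), so a shift in time cannot be told apart from the exposure, because the labels give no time of collection. The exposure, the handling before death and the dissection stay open.

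Oligodendrocyte and myelin markers were lower by a score of -0.28 ± 0.06 SE. With the share of reads on genes as a covariate the difference was -0.25 ± 0.07 (camera adjusted p = 1.26e-11, and 0.295 with an estimated correlation). It was over 2 SE whichever of the 11 libraries was left out, but least clearly without control 2 (-0.25 ± 0.11 SE). No p was computed for the fits with a library left out. Without control 2 the shares were 83.1% to 89.5% in control and 76.8% to 83.8% in toxicant libraries. These ranges barely overlap, so that fit cannot tell the share apart from the exposure. With the GC trend removed the difference was -0.27 ± 0.06 (camera adjusted p = 1.88e-15 at the preset correlation). No p with an estimated correlation was computed for that setting, so this small p is not to be read as its strength. A lower share of all non-neuronal cells would lower the precursors too, and their score was lower by -0.03 (exact permutation p = 0.0216). The mature score fell further than the precursor score (exact permutation p = 0.00433, adjusted p = 0.0216 over 5 cell types). It also fell further than the astrocyte score (-0.10, exact permutation adjusted p = 0.0379). The lists may differ in how specific their members are to a cell type, so these comparisons do not exclude a lower share of all non-neuronal cells. The microglia (-0.18), endothelial (-0.15) and pericyte (-0.12) scores were also lower, and their distance from the oligodendrocyte score did not pass the test (exact permutation, adjusted p = 0.162 to 0.232), so a lower share of several of these cell types stays open. A smaller amount of white matter in the dissected tissue was not tested and stays open beside an effect of the exposure on oligodendrocytes.

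Ribosomal protein and respiratory chain genes were lower and nuclear RNA higher, and these scores followed the share of reads on genes. With that share as a covariate the ribosomal median went from -0.26 to -0.011, while the median SE of its members went from 0.13 to 0.06, so the call ended because the difference vanished and not because the error grew. The ribosomal median lay at percentile 0 of 10000 random lists matched on exon length, but such lists lack the correlation between ribosomal genes (0.797), and the score difference was -0.19 ± 0.11. With the GC trend removed it was -0.14 ± 0.09 (camera adjusted p = 1.81e-06 at the preset correlation). Both differences were under 2 SE, so exon length and GC content cannot be told apart from the exposure. This pattern may therefore reflect how many reads fell outside annotated exons, whose own difference between the groups had an exact permutation p = 0.0714, and whether the exposure changed that share stays open.

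Chance could not be excluded for the 5 counts that other splits of the libraries could test. For genes past the adjusted threshold the comparison says nothing about chance, since a real count of 0 is reached by 100 of 100 splits by construction; the highest other split gave 4331. For genes at an unadjusted p under 0.05, 9 of 100 splits gave as many as the real 2737 (highest other 6909), and for lists called by camera 31 of 100 gave as many as the real 9 (highest other 21, median 6). With the first residual component as a covariate 9 of 100 gave as many as 6538 (highest other 8032), and with sample weights 6 of 100 as many as 9553 (highest other 10053). Without control 2, 2 of 100 splits gave as many as 4932 (highest other 7404), which decides nothing, since that library was chosen for its effect on the count. When each split was given its own choice of the library to leave out, 9 of 100 reached the real 4929 among the genes tested in 11 libraries (highest other 7672). The split with 4331 genes set controls 1, 3, 4-5 and 6 and toxicants 1 and 5 against the rest. It points to a structure of the samples, which overlaps with the exposure groups and was not separated from them by a test.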

How the results depend on the processing

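The 12 libraries as deposited, the share of reads on genes, the nuclear RNA list, the GC trend, the recovered reads and the permutation of list scores (also the share with an estimated correlation) were chosen after seeing the data. The causes of the changes below were not tested, unless stated. The count of 0 higher and 0 lower genes became 1 higher with a pseudocount of 0.1 (Gm24447), 2863 higher and 6690 lower with sample weights, 1737 and 4801 with the first residual component, 9 lower with 12 libraries (a copy added to n), 3 lower with the nuclear RNA list (Btg2, Coro6 and Adgrf5, named after their values were seen), and 1 higher and 10 lower at an adjusted p under 0.1. Leaving out 1 library gave 0 to 1153 higher and 0 to 3779 lower, above 0 only without control 2. In the other settings the count stayed at 0. The lists called, 9, became 20 without a filter, 15 with median-ratio scaling, 15 with quantile normalization, 5 with sample weights, 16 with the share of reads on genes, 20 with the nuclear RNA list, 18 with the GC trend removed, 17 with recovered reads, 18 with fry, and 0 with an estimated correlation, 0 with that and the share of reads on genes, and 0 with permuted scores; leaving out 1 library gave 7 to 14 (14 without control 1).

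Of 189 values of the 9 called lists under the settings that keep all libraries, 137 kept direction and call, 45 lost the call and 7 reversed. Adjusted p with an estimated correlation was 0.797 for the oligodendrocyte, microglia, immediate early, endothelial, nuclear RNA and reactive astrocyte lists, 0.829 for the ribosomal, 0.826 for the NRF2 and 0.911 for the respiratory list. By exact permutation of scores it was 0.0606 for the oligodendrocyte, immediate early and endothelial lists, 0.0707 for microglia, 0.0742 for reactive astrocyte, 0.238 for ribosomal and nuclear RNA, 0.212 for NRF2 and 0.413 for respiratory genes. With fry it was 0.136 for ribosomal, 0.310 for nuclear RNA, 0.0603 for NRF2 and 0.217 for respiratory genes. The oligodendrocyte, endothelial, immediate early, reactive astrocyte and microglia lists kept their calls with fry (adjusted p = 0.00859 to 0.0215). With sample weights it was 0.0529 for immediate early, 0.698 for endothelial, 0.333 for reactive astrocyte and 0.0559 for NRF2 genes, and with the first residual component 0.0741 for endothelial and 0.119 for reactive astrocyte genes. At a filter of 1 RPKM it was 0.0582 for reactive astrocyte, 0.0581 for NRF2 and 0.0783 for respiratory genes. Quantile normalization gave 0.0858 for NRF2 and 0.971 for respiratory genes, and 12 libraries 0.0768 for respiratory genes. With the share of reads on genes the direction reversed for ribosomal (0.549), nuclear RNA (0.0998) and respiratory genes (0.00136), and NRF2 was at 0.860. With that share and an estimated correlation adjusted p was 0.295 for oligodendrocyte, immediate early and endothelial, 0.349 for microglia, 0.373 for reactive astrocyte and 0.923 for NRF2 genes, and 0.963 for ribosomal, 0.603 for nuclear RNA and 0.477 for respiratory genes, which reversed. With the nuclear RNA list, respiratory genes reversed (0.711), nuclear RNA was at 0.711 (its own mean being the covariate) and NRF2 at 0.180. With the GC trend removed nuclear RNA was at 0.114, though its median was 0.38 against 0.29 in the main fit.

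Leaving out 1 library moved the adjusted p between 8.35e-06 and 0.0684 for endothelial, 0.00416 and 0.0839 for reactive astrocyte, 0.0207 and 0.0660 for NRF2 and 0.00522 and 0.140 for respiratory genes; the oligodendrocyte, ribosomal, microglia, immediate early and nuclear RNA lists kept their calls. Ache ranged from -0.26 to -0.10 and passed only without control 2. Leaving out control 4 or 5 alone gives the 11 libraries again. Of 1428 values of the 51 tested named genes, 1285 stayed on their side of the threshold, 142 passed it in the same direction (46 without control 2, 45 with sample weights, 45 with the first residual component) and 22 had the opposite sign, of which Npas4 alone passed (0.30 with sample weights). Neither component's permutation p passed in any setting.

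With the replicate block 0 genes and 9 lists were called, and the reactive astrocyte list was at 0.0547. Genes at an unadjusted p under 0.05 were 4664 with that block and 2737 without it. Residuals of same-numbered samples correlated at 0.62, 0.28, -0.30, 0.32, -0.22 and 0.27, with control 4-5 used for 2 of these. Samples of different numbers correlated at -0.65 to 0.50. The ranges overlap, so these values do not settle whether the numbers pair the samples. Depth limits genes near the filter: Snord91a had a mean of 4.82 reads per library, and Chat 1.55.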

Other observations

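The tests of small noncoding RNA and of pituitary hormone genes were chosen after their values had been seen.

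With the share of reads on genes in the model, an alternative chosen after seeing the data, camera called 16 lists, among them groups not called without it. The 13 mitochondrially encoded genes, whose median log2 fold change was -0.11 without it (camera adjusted p = 0.825) and 0.06 without it and control 2, had a median of -0.30 (adjusted p = 3.03e-08). Dentate granule cell markers had a median of -0.24 and interferon response genes one of -0.20 (adjusted p = 0.000762 each), and the circadian clock genes one of -0.12 (adjusted p = 0.0186). Genes of the unfolded protein response (median 0.10, adjusted p = 0.000762) and markers of GABAergic interneurons (median 0.10, adjusted p = 0.000854) were higher in that fit. Red blood cell genes were lower in 5 of 6 cases without the covariate (camera adjusted p = 0.0765), and 5 fell when adjusted over the list alone. With the covariate and an estimated correlation 0 lists were called (smallest adjusted p = 0.295), so these calls rest on the preset correlation.

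Small noncoding RNAs, which carry no poly(A) tail in their mature form, were higher in toxicant libraries in 61 of 74 genes past the filter, with a median log2 fold change of 0.48. The class score was -1.50 ± 0.213 (SD, n = 5) in control and -0.863 ± 0.368 (SD, n = 6) in toxicant libraries (exact permutation p = 0.00866), with 5 of 6 toxicant libraries above the highest control. With the share of reads on genes in the model the difference was 0.46 ± 0.21 (SE). The hypothesis that toxicant libraries carry more small noncoding RNA as a class may hold, and whether that came from the poly(A) selection or from the tissue was not tested.

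Pituitary hormone genes were detected in some libraries. Gh was at 31.5 RPKM in control 3, 31.0 in control 6 and 3.85 in control 4-5, and at or below 0.270 in the others. Prl was at 3.76, 2.63 and 0.267 RPKM in the same libraries and at most 0.0751 elsewhere, and Pomc at 8.73 and 8.77 RPKM in controls 3 and 6 against at most 1.74 in the others. Cga was at 0.378, 0.481 and 0.179 RPKM in controls 3, 6 and 4-5, at most 0.0342 in the other controls and listed at 0 in the 6 toxicant libraries. The 3 libraries highest in Gh, Prl and Cga were all controls; the exact permutation p of the group difference was 0.0541 for Gh, 0.0281 for Prl, 0.186 for Pomc and 0.0152 for Cga (adjusted p = 0.126, 0.0985, 0.261 and 0.0985 over 7 genes). A candidate explanation is pituitary tissue carried into the dissection of these animals. Gh and Prl ranked the 11 libraries with a Spearman's rho of 0.58 (permutation p = 0.0659), which does not settle it, since most libraries lie near 0 and Pearson's r over such separate levels is not given. Of the 7 hormone genes written for this test, Pomc and Tshb were above 0 in all 11 libraries.

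Control 4 and control 5 are listed as separate animals and hold the same value in every gene, while 0% of detected genes were equal in other pairs of libraries.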
